A study of Mus musculus with 2 samples.

How the data were processed

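RNA of pooled left kidneys and of pooled right kidneys of male mice was hybridised to 2 Agilent arrays, 1 per side. The series description was read as 1 pool of 3 kidneys per side, and its wording leaves this open. Per the labels' protocols, ribosomal RNA was removed, and the remaining RNA was amplified with random primers into labelled cRNA covering whole transcripts. The label field names biotin, while the file headers describe 1 fluorescence channel.

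Per the file headers, the images were read with Agilent Feature Extraction 11.0.1.1, and the deposited intensities are background-subtracted and detrended within each array, with no normalization between arrays. The intensity table the authors deposited for the series equals the processed signal in all 62513 rows of each array, to a relative tolerance of 1e-05. Its column medians are 58.58 (left) and 60.96 (right), on a linear scale with no centring. No array had a saturated spot. The lowest signal of a probe well above background was 33.24 on the left and 27.23 on the right, and the additive error estimated by the software was 7.0 and 5.63. Signal over background sets what can be read: the 75th percentile of the processed signal was 436.5 on the left and 435.4 on the right.

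From these intensities, log2 processed signal minus the 75th percentile of each array was computed. Control spots, spots of probes named as negatives (20 probes with 60 spots each, treated as negatives by name) and spots with an outlier flag (34 left, 20 right) were left out, and spots of a probe were averaged on the log2 scale. Differences are left minus right, over probes well above background on both arrays, and 2-fold means an absolute log2 difference of 1 or more. A signal below background was bounded by the higher of the lowest signal well above background on that array and the probe's own signal, and folds against it are written as at least that large. No p-value was computed, as each side has 1 array. Classes of probes were set against 10000 random lists of the same size, drawn within 20 bins of mean signal. Shares have exact (Clopper-Pearson) 95% intervals.

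Gene names came from RefSeq accessions carried by 123 probes, of which 116 matched the NCBI gene table of assembly GRCm38.p6, giving 112 symbols. That table was used for names only, since the array grid names another build. The other 59593 probes have no gene name here and are given by class, read from their probe names, or by probe identifier. As fixed before the data were examined, the genes named are the 10 in each direction with the largest difference that keeps its sign under normexp and quantile normalization and whose probes all go the same way, the 5 lincRNA probes in each direction chosen likewise, 2 to 4 members of each gene list, and up to 3 genes in each direction above background on 1 array only. Genes with replicate spots are also named outside that rule, because they alone have such spots. The 32 gene lists fixed beforehand had 0 members with a named probe, so their shifts were not computed.

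Alternatives were median scaling, quantile and cyclic loess normalization, normexp background correction with an offset of 50, the authors' table without scaling, other background filters (among them a signal at least 4 times the dimmest probe well above background), other size limits of 1.5-fold and 3-fold, and another detection flag. The planned normexp input, the mean spot signal, is not among the columns used here, so the median spot signal and the median local background took its place. The offset of 50 is added before the log2, so it shrinks differences of dim probes by construction. For scale, the median processed signal was 66.27 on the left and 68.36 on the right. Added after seeing the data were a correction by the median of the 18 nearest tested probes, 4 detection limits set on negative spots, and keeping flagged spots of the genes with replicate spots. Python 3.11.15 (numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, matplotlib 3.10.9) and R 4.3.3 with limma 3.58.1 were used. Tested on simulated differences between left and right kidney over 35367 probes, with normal noise of the SD seen in each of 12 brightness ranges (0.142 to 0.394), the 2-fold count recovered 100% of 200 probes changed 4-fold and called 86 unchanged ones, and 2 of 40 unshifted random lists fell outside the central 95%. A 4-fold change lies far past the limit for such noise, so this says nothing of changes near 2-fold. The simulated noise was normal and had no marks on the surface, so the 86 calls need not describe these arrays.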

Results

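Long noncoding RNA and mRNA levels were measured in left and right kidneys of male mice with a 1-colour Agilent oligonucleotide array. Kidney RNA was pooled, 3 left kidneys into 1 sample and 3 right kidneys into the other, as the series description was read here, and each pool was put on 1 array. Each array carried 62513 spots, among them 59994 spots of 59709 distinct probes that are neither controls nor named as negatives. The comparison implied by this design is left against right kidney, for noncoding and coding transcripts alike. With 1 array per side there was no replicate of either kidney, so no test could be made, and differences are given as values of these 2 arrays. The number of arrays limits the precision of every value below.

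Probes of each class on the array gave signal with kidney RNA, at different frequencies. Nonspecific signal was not separated from that of the intended transcripts. Among the transcript probes with an array design number, 63.04% were well above background on the left array and 68.08% on the right, and among probes with a transcript accession 61.33% and 65.26%. Mouse lincRNA exon probes, which target exons of long intergenic noncoding RNAs, were above background in 50.56% on the left (95% interval 48.88 to 52.24) and 56.26% on the right (54.59 to 57.92). Probes for mouse lincRNAs were above background in 30.97% on the left and 37.92% on the right, and probes named for human lincRNAs in 31.14% and 36.48%. Ultraconserved element probes, for genomic stretches identical between distant mammals, were above background in 30.35% (27.46 to 33.37) on the left and 35.55% (32.52 to 38.67) on the right. Spots of the 20 probes named as negatives passed the same criterion in 6.5% of 1200 cases on the left and 9.58% on the right. Over all 59701 probes with an unflagged spot, 36045 (60.38%) were above background on the left, 39105 (65.5%) on the right and 35367 (59.24%) on both. Another 678 were above background on the left array alone and 3738 on the right alone. These one-sided counts depend on the limit: at the 95th percentile of each array's spots named negative they were 1397 and 1612, and with 18 of those 20 probes 1693 and 2961. The intervals are exact binomial intervals and cover counting error only.

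**Figure D1:**
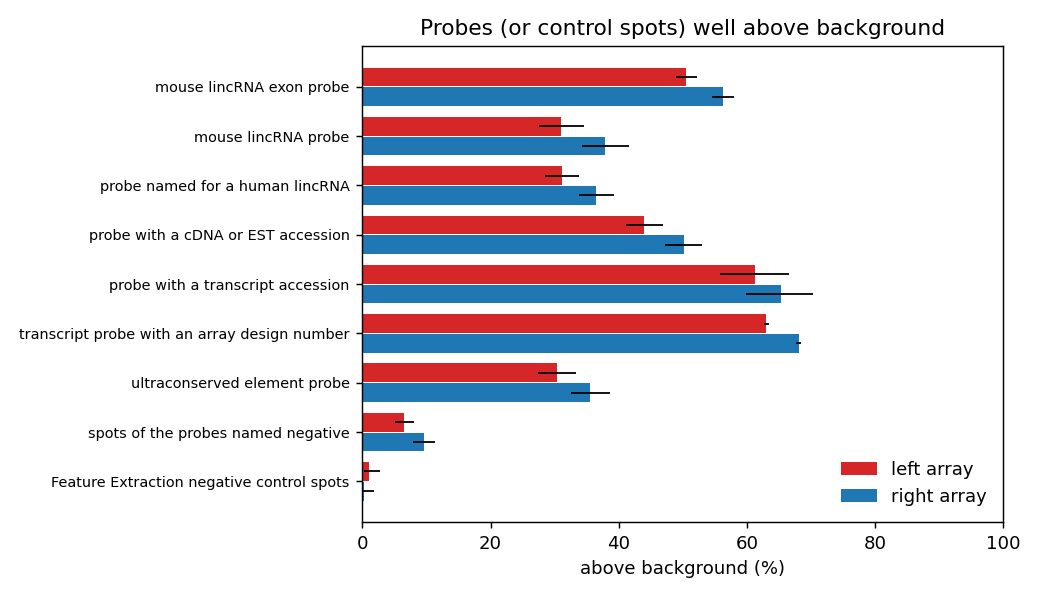
Share of probes well above background (horizontal axis, percent) for each class of probe and for 2 kinds of negative spots, on the left (red) and right (blue) array, with exact 95% binomial intervals as lines. Counted per probe and not per element, transcript probes with an array design number were the most often detected class (63.04% left, 68.08% right). The spots of the probes named negative were at 6.5% and 9.58%.

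Most genes with a name differed little between the left and right arrays, as did most probes. Of 112 named genes, 71 were above background on both arrays, and none of them differed 2-fold. Over all 35367 probes above background on both arrays, 1.08% were 2-fold and 5.109% 1.5-fold apart. The absence of a 2-fold gene among 71 therefore does not set named genes apart. Of these 71 genes, 54 lay within 1.2-fold, 2 were at least 1.5-fold higher on the left and 3 at least 1.5-fold higher on the right. With normexp these counts were 1 and 0, and after correction for position on the array 1 and 2. The highest left signal relative to the right belonged to B020031M17Rik, at 1.89-fold (log2 difference 0.92), and the lowest to Gm20854, whose signal was 1.72-fold higher on the right (log2 difference -0.78). For comparison, the SD of the left minus right difference was 0.142 among the 2948 probes in the brightest range, where B020031M17Rik lay, and 0.394 in a dim range of log2 signal 5.65 to 6.09.

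Genes printed in 20 spots per array, many of them housekeeping genes, gave the only left against right differences of genes with a measured spot-to-spot error. Hsp90ab1, a cytosolic chaperone, was higher on the left, with a log2 difference of 0.26 ± 0.04 (SD of 16 spot pairs). Actb, the cytoskeletal beta-actin, was 1.15-fold higher on the left at 0.20 ± 0.07 (SD, 19 spot pairs), and both genes were higher on the left in every pair used. Under quantile normalization Hsp90ab1 stood at 0.17 and Actb at 0.12. With flagged outlier spots kept, added after seeing the data, their 20 pairs gave 0.29 ± 0.07 and 0.22 ± 0.13. Tfrc, the transferrin receptor that takes up iron, was lower on the left at -0.12 ± 0.08 (SD, 19 spot pairs), and 17 of its 19 pairs were higher on the right. Gapdh of glycolysis stood at 0.03 ± 0.06 over 17 pairs, and B2m, the light chain of class I histocompatibility molecules, at 0.01 ± 0.04 over 17 pairs. Both lay within their spot spread and turned negative under cyclic loess, at -0.03 and -0.05. Of the 14 such genes above background, 11 had a positive and 3 a negative difference, and 10 differed by more than 1 SD of their spot pairs, or 7 with flagged spots kept. The median difference was 0.06. Probes of any kind in the 3 brightest ranges of 12, where nearly all these genes lay, had medians of 0.062, 0.053 and 0.059. Under cyclic loess, which removes that trend, 7 of the genes were positive and 6 negative, with a median of 0. Gusb (lysosomal beta-glucuronidase), G6pd2, Rpl13a (a ribosomal protein) and Ppia (cyclophilin A) lay between 0.09 and 0.11, Gk (glycerol kinase), Tuba1b (alpha-tubulin) and Tbp (the TATA-binding protein) between 0.05 and 0.06. Under cyclic loess and quantile normalization Gusb, Rpl13a and Ppia lay between 0.028 and 0.041. Tbp turned negative under cyclic loess and quantile normalization, Tuba1b after correction for position. Nono and Hprt were at -0.03 each. Ldhal6b, a lactate dehydrogenase-like gene, was not well above background on the left array in any of 19 spots. Spot pairs on the same arrays share the pool, its amplification and labelling, and the hybridisation. Their spread therefore covers spot noise only and holds no variation between mice or between preparations. Robust SDs, from the median absolute deviation, were also taken for differences of other probes within 0.25 log2 of a gene's brightness. They were 0.11 at Hsp90ab1, 0.127 at Actb and 0.142 at Tfrc.

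**Figure D2:**
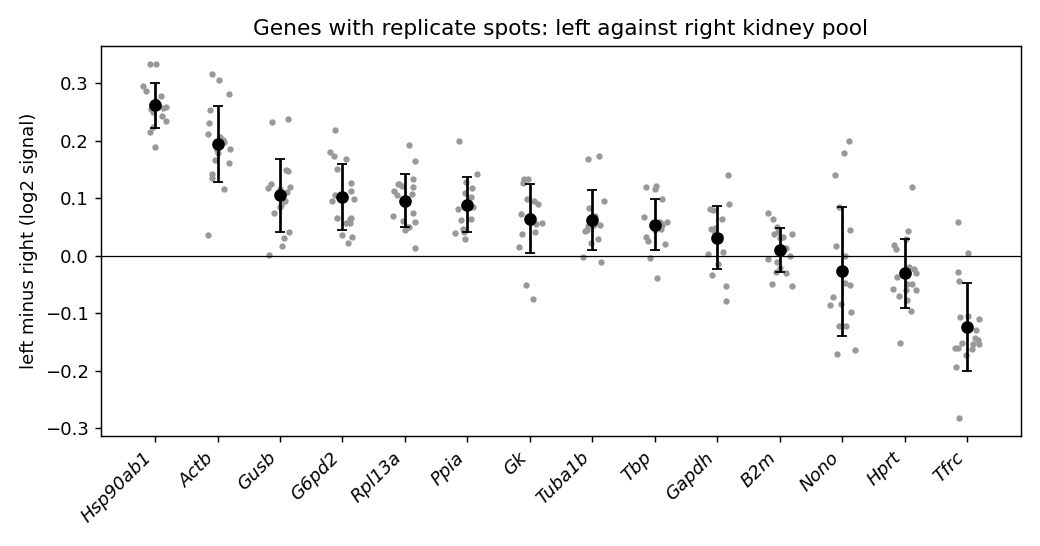
Left minus right difference in log2 signal (vertical axis) for 14 genes with 14 to 19 usable spots on each array (horizontal axis), with each spot pair in grey and the mean ± SD of the pairs in black. Hsp90ab1 (0.26) and Actb (0.20) stood above 0 in every pair and Tfrc (-0.12) lay below 0 in 17 of 19.

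The named genes with higher signal on the left were of mixed kinds. After B020031M17Rik came Gm16513 at 0.60 (1.52-fold), then the vomeronasal receptor genes Vmn1r62 (0.55), Vmn1r257 (0.34) and Vmn1r135 (0.33), which encode pheromone receptors of the nose. Gm20806 (0.35), BC147527 (0.30) and 4930526I15Rik (0.19), besides Hsp90ab1 and Actb, completed the 10. On the right, Gm20854 was followed by another vomeronasal receptor gene, Vmn1r111, at -0.72 (1.64-fold higher on the right), and by Gm10147 at -0.70 (1.63-fold). Ccl28, a chemokine of mucosal epithelia, was 1.39-fold higher on the right (-0.48), and Jrkl was 1.34-fold higher (-0.42). Spry3, of the sprouty family of receptor tyrosine kinase antagonists, stood at -0.38, Gm13304 at -0.35, Csprs at -0.34, the Y-linked spermatid gene Ssty2 at -0.34 and Fam205a2 at -0.30. Apart from Hsp90ab1, Actb and 4930526I15Rik, each of these values rests on 1 spot per array. Vmn1r62, Gm20806, Vmn1r257, Vmn1r135, Gm20854, Vmn1r111, Gm10147, Spry3, Csprs and Ssty2 were too dim for the stricter background filter. Among them are all 3 genes at least 1.5-fold higher on the right. The normexp offset shrinks differences of such dim genes by construction. With normexp background correction Gm16513 moved to 0.42, Vmn1r62 to 0.20, Vmn1r257 to 0.08, Gm20806 to 0.11, Vmn1r135 to 0.18, Gm20854 to -0.33, Vmn1r111 to -0.32, Gm10147 to -0.19, Spry3 to -0.18, Csprs to -0.21 and Ssty2 to -0.08. After correction for position on the array Gm16513 stood at 0.56, Vmn1r62 at 0.32, BC147527 at 0.14, 4930526I15Rik at 0.06 and Gm13304 at -0.22.

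Detected on 1 side alone were 4 named genes. H2ac23, a histone H2A gene, was above background on the left and not well above background on the right, at least 1.43-fold higher on the left. Gm14819 was above background only on the right, at least 1.59-fold higher there. Hhipl2 and Vmn1r63 were also above background only on the right, too dim for a bound above 1. The bounds hold for the processed signal alone, without the normexp offset, which shrinks dim differences by construction. With normexp the log2 differences of H2ac23 and Gm14819 were 0.316 and -0.275, smaller in size than their log2 bounds of 0.519 and 0.666. Each of these 4 genes rests on 1 spot per array. The probes of Gm3286 and of Ppp2r3d went different ways, so neither was named for its size, and both count among the 71 genes with the mean of their probes (-0.23 and -0.11). The 32 gene lists fixed for kidney cell types, neighbouring tissues, stress responses and pathways held 409 genes, and 0 of these could be matched to a named probe, so no list, cell type marker included, has a value.

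Across all probes above background on both arrays, 190 probes were at least 2-fold higher on the left and 192 at least 2-fold higher on the right, together 1.08% of 35367. Mouse lincRNA exon probes contributed 11 on the left and 14 on the right, which is 1.47% of 1701 (95% interval 0.95 to 2.16). Mouse lincRNA probes contributed 3 and 1 of 208, ultraconserved element probes 0 and 5 of 281, and transcript probes with an array design number 172 and 170 of 32105 (1.07%). The share did not separate the classes, since the interval of each noncoding class included 1.07%. The total was 102 with normexp background correction, whose offset shrinks dim differences by construction. It was 105 with a stricter background filter and 5269 with no background filter. The 2-fold probes lay mostly among dim probes, with 1 on the left and 0 on the right among the 2948 brightest.

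The lincRNA probes with the highest left over right ratio were mouselincRNA0561+_P1 (3.90-fold), MM9LINCRNAEXON10212+_P1 (3.65-fold), mouselincRNA0713+_P1 (3.46-fold), humanlincRNA2039-_P1 (3.12-fold) and MM9LINCRNAEXON11321-_P1 (2.97-fold). Under normexp only MM9LINCRNAEXON11321-_P1 of these stayed 2-fold apart, at a log2 difference of 1.11, and after correction for position it stood at 0.99. The 6 nearest probes of MM9LINCRNAEXON11321-_P1 and humanlincRNA2039-_P1 had medians of 0.71 and 0.77. The scaled log2 signals of mouselincRNA0561+_P1 and MM9LINCRNAEXON10212+_P1 on the right were -3.763 and -3.693. The lowest signal well above background was -3.948 on the right array and -3.664 on the left. Both probes thus lay near the right limit and below the left one. In the other direction, MM9LINCRNAEXON10840-_P1 was 9.60-fold higher on the right, MM9LINCRNAEXON10991+_P1 4.40-fold, MM9LINCRNAEXON10788-_P1 4.18-fold, MM9LINCRNAEXON11754-_P1 3.76-fold and MM9LINCRNAEXON10649-_P1 3.41-fold. Under normexp the log2 difference of MM9LINCRNAEXON10840-_P1 was -1.94 against -3.26, that of MM9LINCRNAEXON10788-_P1 -1.25 against -2.06, and that of MM9LINCRNAEXON10649-_P1 -0.80, short of 2-fold. The tested probes next to MM9LINCRNAEXON10991+_P1 and MM9LINCRNAEXON10788-_P1 on the array were shifted the same way, with median log2 differences of -1.81 and -1.39 over the 6 nearest. Each of these lincRNA values rests on 1 spot per array.

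**Figure D3:**
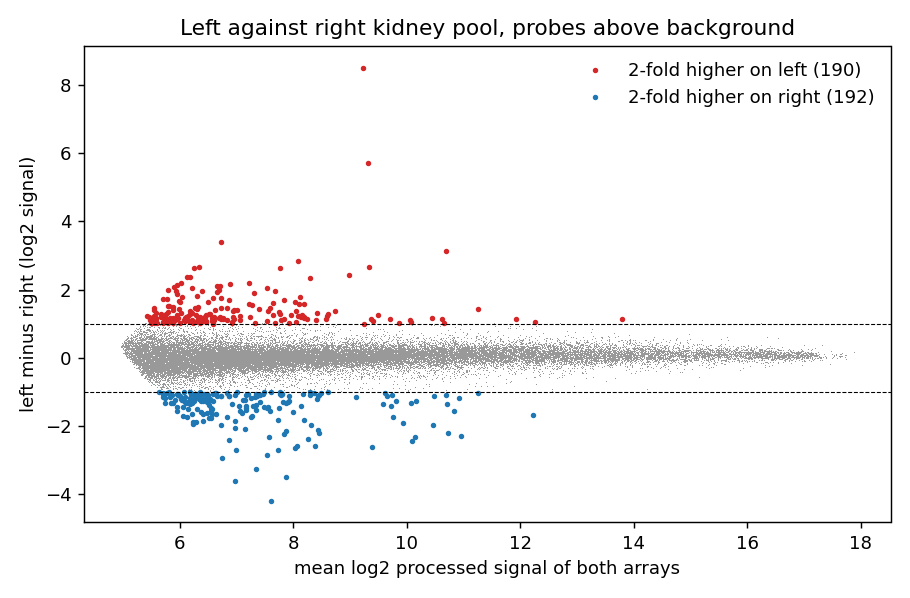
Left minus right difference in log2 signal (vertical axis) against the mean log2 processed signal of both arrays (horizontal axis) for 35367 probes above background on both. Red points mark 190 probes at least 2-fold higher on the left, blue points 192 at least 2-fold higher on the right, grey points the rest, and dashed lines the 2-fold limits.

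As whole classes, ultraconserved element probes and mouse lincRNA exon probes had slightly lower signal on the left. The median difference of the 281 ultraconserved element probes was -0.059, at the 0.1 percentile of random probe lists of the same size and brightness, whose central 95% of medians lay between -0.041 and 0.028. The 1701 mouse lincRNA exon probes had a median of -0.024, also at the 0.1 percentile, with the central 95% of random medians between -0.016 and 0.01. With normexp the medians were -0.017 and -0.007, at the 1.1 and 0.05 percentiles. After correction for position on the array the lincRNA exon probes stood at the 8.94 percentile. Medians of mouse lincRNA probes (-0.01), probes named for human lincRNAs (-0.04) and cDNA or EST probes (-0.01) lay within the central range of their random lists. The percentiles describe these 2 arrays and are not tests between kidneys.

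Signals of the 2 kidney pools ran closely together over the 35367 probes. Pearson's r across probes was 0.9945 and Spearman's rho 0.9878, where probes are not independent replicates. The SD of the left minus right differences was 0.308. Replicate spots of the 14 replicated genes above background had SDs of signal between 0.019 and 0.10 within an array, without flagged spots and at higher brightness than most probes. These are not SDs of differences. With flagged spots kept, the SD of the left minus right spot pairs had a median of 0.077 over the 14 genes. The median robust SD of other probes at their brightness was 0.134, and 11 of the 14 genes lay below that of their own range. Left and right pools shared 1 slide scan and differed in array position, so side and position on the slide cannot be told apart.

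**Figure D4:**
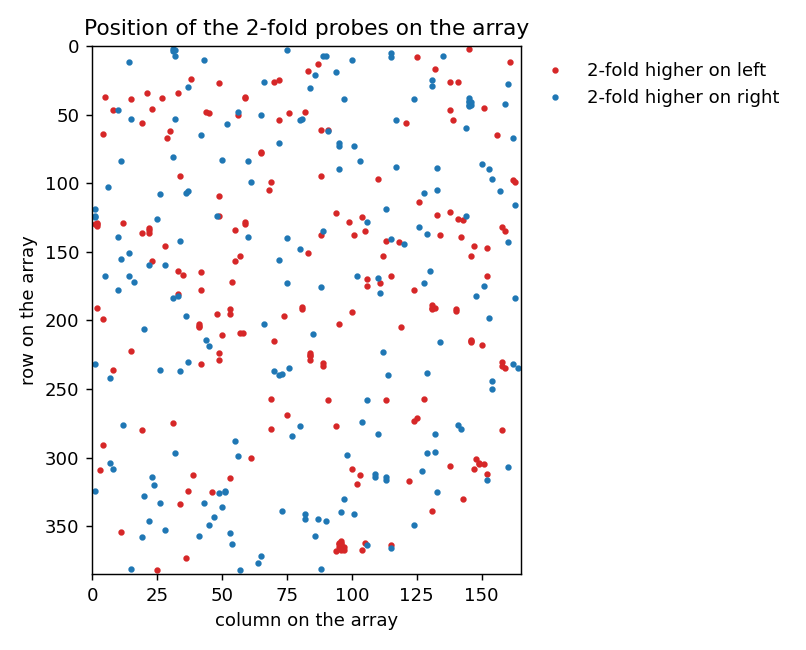
Array row (vertical axis) against array column (horizontal axis) of the 190 probes at least 2-fold higher on the left (red) and the 192 at least 2-fold higher on the right (blue). Of these, 52 on the left and 31 on the right had a 2-fold probe of the same direction among their 6 nearest tested probes.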

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

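Control probes and probes named as negatives enter no comparison of kidney transcripts, and serve only as measures of background and spot noise. Among 56 of them with at least 10 spots, 7 were well above background in over 50 percent of their spots on both arrays, leaving out the bright corner spots. The spike-in probe ERCC-00062_278 was above background in 100% of its 35 spots on both arrays, with median signals of 275.6 on the left and 276.7 on the right. The E1A spike-in probes (+)E1A_r60_3 and (+)E1A_r60_a22 were each above background in 91.4% of 35 spots on the left, and in 97.1% and 100% on the right. ETG05_36762 and ETG05_66023 were each above background in 91.7% of 12 spots on the left and 100% on the right. MM9NEGATIVE009 was above background in 55% of 60 spots on the left and 88.3% on the right, and MM9NEGATIVE020 in 61.7% and 83.3%. Each of the other 18 probes named negative was above background in at most 2 spots on the left and 3 on the right.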

How the results depend on the processing

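The count of 2-fold probes stayed within 1.5 times of 382 under median scaling (381), quantile normalization (405), cyclic loess (390), the authors' table without scaling (384) and, chosen after seeing the data, correction by the nearest 18 probes (347). It moved to 102 (49 higher on the left, 53 on the right) with normexp, which changes the background method, its inputs and the offset together. The offset shrinks dim differences by construction, and its share in the fall was not separated from the other changes. The count was 105 (52 and 53) with the stricter filter, which tests 23053 probes, and 5269 (2056 and 3213) with no background filter over 59701 probes. At 1.5-fold it was 1807 (873 and 934) and at 3-fold 97 (44 and 53). Pearson's r was 0.9966 with normexp, 0.9855 without a filter and 0.9958 with the stricter filter, and the SD of the differences was 0.595 without a filter. Detection totals on the left, right and both arrays stayed within 1.5 times under each flag and limit tried, while probes detected on 1 side alone ranged from 678 to 1835 (left) and 1612 to 5186 (right). The 20 genes and 10 lincRNA probes named for their size, chosen for keeping their sign under normexp and quantile normalization, kept it under the alternatives run. Among all 71 named genes above background, 18 changed sign under at least 1 alternative, 10 of 71 under cyclic loess and 11 under quantile normalization. Of the values of the genes and probes named for size, 18 for genes and 11 for lincRNA probes were counted as moved, all under normexp or the position correction. The limit was narrower for genes. After position correction Gm20806, from 0.351 to 0.249, counted as moved, while mouselincRNA0713+_P1, from 1.789 to 1.521, did not. Some counted moves were thus smaller than the SD of 0.308 over all probes. Among the genes with replicate spots, Tbp turned from 0.054 to -0.005 under cyclic loess and -0.007 under quantile normalization (the cause was not tested). B2m turned from 0.01 to -0.047 and -0.034 under the same 2, and Gapdh from 0.031 to -0.025 under cyclic loess. Besides these 2 values of Tbp, 17 values in this group moved by more than the SD of their spot pairs, among them values of Hsp90ab1 and Actb. The normexp alternative used median in place of mean spot signals. Detection by the authors' own filter was not run because their table lists all spots, and no alternative was run for the gene lists, which have no named member. No paired analysis was possible because each side has 1 array. Signal over background limits the dim probes, where most 2-fold differences lie.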

Other observations

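The tests in this part were chosen after the result was seen, except the detection counts with the other flag, which were planned. Many noncoding elements have a pair of probes whose names end in + and -, read here as the 2 strands. Of 481 ultraconserved elements, 191 had 1 strand above background on both arrays, 45 had both strands and 245 had neither. Of 1728 mouse lincRNA exons, 909 had 1 strand, 396 both and 423 neither. With detection on both arrays, both strands were detected about as often as independent detection of each strand gives, which is 41.0 ultraconserved elements and 416.6 lincRNA exons. On single arrays, 51 ultraconserved elements had both strands on the left against 44.3 under independence, and 74 on the right against 60.8. For lincRNA exons these were 425 against 439.7 and 539 against 545.4. The left and right arrays put 85.2% of the ultraconserved elements and 83.6% of the lincRNA exons in the same strand state. Among 608 elements named for human lincRNAs, 66 had both strands against 53.6 under independence.

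Some single probes, picked after their values were seen, stood far from the rest. ASMM9PARTA031791 was 364.2-fold and ASMM9PARTA027436 51.9-fold higher on the left, while their 6 nearest probes had median log2 differences of 0.27 and 0.14. The cDNA probe AK007918_P1 was 8.8-fold higher on the left. ASMM9PARTA005626 was 18.2-fold higher on the right, with -1.61 over its 6 nearest probes, and ASMM9PARTA025269 12.2-fold. Each value rests on 1 spot per array. Among gene families grouped after their names were seen, 6 of 12 vomeronasal receptor genes were above background on both arrays, with differences from -0.72 to 0.55, and 1 of 4 Y-linked spermatid genes was.

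For the 382 probes that were 2-fold apart, the first pattern weighed, marks on the array surface may account for part: 83 had another 2-fold probe of the same direction among their 6 nearest, against a median of 12 and a highest value of 29 in 1000 random draws matched on brightness. Marks wide enough to shift the median of the 6 nearest tested probes by 0.3 or more are not the source of most. That median was shifted so far the same way for 15.4% of the 382 probes (exact 95% interval 12 to 19.5). Smaller marks can leave that median unchanged, so they stay open. Noise of single spots stays open: 2 of 491 replicate spot pairs, outlier flags included, were 2-fold from their own probe mean against 2.99 expected at the rate of the tested probes. Without flagged spots it was 0 of 444 against 2.78, and even a count of 0 allows 3.69. The SD of spot pairs was below the robust SD of other probes of the same brightness for 18 of 23 replicated probes. Over the 14 replicated genes above background its median was 0.077 against 0.134, but most 2-fold probes are dimmer than these genes. A difference between left and right kidneys also stays open, untested with 1 pool per side.

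The excess of probes above background on the right, 3060 more than on the left, is the second pattern. Unequal detection limits may account for part of it, and how much stays open. With each array's limit at the 95th percentile of its spots named negative, the excess was 215, but that limit rests on MM9NEGATIVE009 and MM9NEGATIVE020, which carry signal themselves. Over the other 18 negative-named probes the excess was 1268 (41.4% of 3060) at the 95th and 1753 (57.3%) at the 99th percentile, against 2469 with the other detection flag and 3822 with a limit from the Feature Extraction negative controls. A larger number of transcripts in the right pool was not tested.

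The lower left signal of ultraconserved element probes is the third pattern. It is not accounted for by a trend across the 20 brightness bins, since the random lists were matched on them. Cyclic loess could for the same reason hardly change the percentile, and gave a median of -0.055 at the 0.13 percentile. Narrower bins were not tried for these probes, so a steep trend within a bin stays open. After correction by the 18 nearest probes the median was -0.069, at the 0.17 percentile. Marks wide enough to shift the median of those probes therefore do not account for it, while smaller marks stay open. Nonspecific signal on the right array stays open: spots of negative-named probes above background on both arrays had a median difference of -0.123, but all 67 come from 2 probes, too few to set against other probes. Kidney side stays open, untested.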
